A study of Mus musculus with 2 samples.

How the data were processed

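RNA was sequenced from cells labelled as Sertoli cells, sorted from the testes of control and MafB-cKO mice, with 1 library per group and RNA of 3 mice pooled in each. Per the labels' protocols, total RNA was extracted from cells sorted by fluorescence, and libraries followed standard Illumina protocols. Per the submitters' processing notes the genome build was mm10; the aligner, the counting tool and the annotation are not given in the sources used here. Per the file headers, the deposited values are RPKM per gene symbol. From the values themselves, the authors' RPKM had afterwards been quantile normalized: the sorted values of both libraries were identical at 100% of ranks and each library summed to 407039 RPKM. This step forces the libraries to the same distribution, removes differences in their overall distribution, and leaves values that are no longer proportional to reads. The depth of each library is therefore unknown, no counting interval can be given, and a gene listed at 0 gives no upper limit.

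In each library 20575 of 38924 genes were listed at 0. The lowest values above 0 ran nearly in alphabetical order of gene symbol, so they stand for tied zeros: 1028 genes up to 0.0229 RPKM in the control and 1976 genes up to 0.0767 RPKM in MafB-cKO. Genes at 0 or at a tied zero are called listed at 0, and no fold is printed for them. Where their mean passes the minimum level, they still enter the counts past 2-fold and the list medians through the pseudocount. With ties included, 21603 genes were at 0 in the control and 22551 in MafB-cKO. As both libraries hold such a block, further libraries were likely part of the normalization; they are not analysed here.

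The log2 fold of a gene was log2((MafB-cKO + 1)/(control + 1)), with a pseudocount of 1 RPKM, on values as deposited. Counts of genes past 2-fold and gene lists used genes with a mean over both libraries of at least 1 RPKM. With 1 library per group no test was possible, so no p-value, SD between replicates or count of significant genes is given. For each gene list, the median log2 fold was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins; lists with under 5 measured members got no percentile. For a test chosen after the values were seen, 10000 lists were matched to the macrophage markers on GC content, transcript length and level, each marker replaced by 1 of the 100 nearest genes outside the macrophage lists. The 31 gene lists, the design, the rule for named genes and most alternative settings were fixed before the data were examined. Of 603 list symbols, 8 were matched through synonyms and 8 were not found. Coordinates and exons came from GENCODE M21 on GRCm38, the same assembly as mm10, in which 35458 of the 38924 symbols were found.

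Named genes were chosen by rule: Mafb and the MAF family; the 12 largest log2 folds each way among genes with a mean of at least 5 RPKM, leaving out gene models, microRNAs and small nucleolar RNAs; up to 4 members with the largest absolute log2 fold in each list; the 5 highest genes of each library; and Sox9, Amh, Wt1, Gata4, Fshr, Ar and Cldn11. Genes outside the rule are said to have been chosen after their values were seen. Another 9 lists were written after the values had been seen: seminal vesicle secretory transcripts, cardiac muscle transcripts, resident macrophage markers, MHC class II and monocyte-derived macrophage markers, the UDP-glucuronosyltransferase 1 family, other sterol-regulated genes, the kallikrein 1 family, mitochondrially encoded mRNAs and Sertoli-restricted transcripts. Several of their members had prompted them, and Cd209f and Cd209g were removed from the resident macrophage list after their values were seen. Sc4mol was likewise removed from the other sterol-regulated genes, as it stands in the fixed cholesterol list. Last, 2 lists of 10 further Leydig and 10 further Sertoli cell markers were written with the bounds of their tests, from genes in no other list whose values had not been looked at; the pattern they test was already known.

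Alternative settings fixed in that way were pseudocounts of 0.1 and 5, scaling by the median gene ratio, by the upper quartile and by the trimmed mean of M values (30% trimmed by ratio, 5% by level), no minimum level, a mean of at least 5 RPKM, thresholds of 1.5-fold and 4-fold, and leaving out germ cell, leukocyte and macrophage marker genes. Chosen after seeing the data were setting tied zeros to 0, using 10 level bins, the macrophage list without complement C1q, MHC class II and Cd74 genes, and the macrophage, interferon, inflammatory and MAFB-dependent lists without members found in another of the 31 lists. With no replicates, a log2 value was counted as unmoved when it moved by under 0.46, the smallest SD of log2 folds between genes in any range of levels; this bound too was set after seeing the data.

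The list method was tested on simulated data with the 11786 genes of the comparison. Of 100 lists with no seeded shift, 2, 1 and 3 fell outside the central 95% at sizes of 5, 15 and 25 genes. With a seeded log2 shift of 0.5, 53, 90 and 96 of 100 were found at these sizes, and with a shift of 1, 93, 100 and 100. Simulated folds were drawn independently for each gene, so these rates do not hold for lists whose genes move together. They were drawn from a normal distribution with the SD of the gene's level. The shape of the real folds was not reproduced, so the rates may differ on these data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.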

Results

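RNA sequencing was used to compare cells sorted from the testes of mice lacking MAFB with cells sorted from control mice, all labelled as Sertoli cells, the somatic cells that support germ cells inside the seminiferous tubule. MAFB is a basic leucine zipper transcription factor of the large MAF family. The conditional knockout mice (MafB-cKO) carried a loxP-flanked Mafb allele and a tamoxifen-activated Cre recombinase, and the controls were wild type. Mice of both groups were C57BL/6 and received tamoxifen at 75 mg/kg on 5 days from 6 weeks of age. Busulfan, an alkylating agent that depletes germ cells, followed at 20 mg/kg at 8 weeks, and cells were sorted 5 weeks later, at 13 weeks of age. Each group was 1 library, made from pooled RNA of 3 mice. There was therefore no replicate check on any difference given here, and no p-value or error could be computed. The values were RPKM (read counts scaled to transcript length and to the number of mapped reads) for 38924 genes. The sorted values of the libraries were identical at 100% of ranks, so each summed to 407039 RPKM and the sequencing depth behind a value is unknown. Differences are given as log2 folds of MafB-cKO over control on RPKM + 1, a scale that understates differences of weakly expressed genes.

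The targeted gene was lower in the knockout library. Mafb, on chromosome 2 from 160363703 to 160367065 on the minus strand of mm10 and annotated with 1 exon, was at 22.7 RPKM in the control and 3.64 RPKM in MafB-cKO, a log2 fold of −2.35 on RPKM + 1. Without the pseudocount, the level was 16.0% of the control's. In which cells the recombinase acts is not given in the sources used here, which limits what the residual level can be read as. The residual 3.64 RPKM was above the values that stand for tied zeros. Among the other MAF genes, Maf was at 6.84 and 8.61 RPKM, Mafk at 6.53 and 10.3 RPKM, and Maff at 5.58 and 7.56 RPKM in control and MafB-cKO. Mafa was listed at 0 in the control and at 1.13 RPKM in MafB-cKO, and Nrl was listed at 0 in both. Over the MAF family and its partners, 7 members were measured, with a median log2 fold of 0.17 at percentile 90.8 of random gene lists. Of the 7, Mafb alone was past 2-fold.

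Outside Mafb, the libraries were alike for most genes. Of 11786 genes with a mean of at least 1 RPKM, 400 were at least 2-fold higher in MafB-cKO and 286 at least 2-fold lower, together 5.82%. In 104 of these genes, 1 library was listed at 0 or at a tied zero, 45 among the higher and 59 among the lower genes. Across genes, which are not independent replicates, the log2 values correlated with a Pearson r of 0.951 and a Spearman rho of 0.930. The SD of the log2 fold between genes was 0.58 at a mean of 1 to 5 RPKM and 0.46 at 5 to 20 RPKM. It was 0.47 at 20 to 100 RPKM and 0.51 from 100 RPKM up. Without the germ cell, leukocyte and macrophage marker genes, 383 genes were higher and 284 lower. These counts describe the pair of libraries and carry no test. They moved by over 1.5 times with the pseudocount, with a higher minimum level and with the fold required, and the lower count also with no minimum level.

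**Figure D1:**
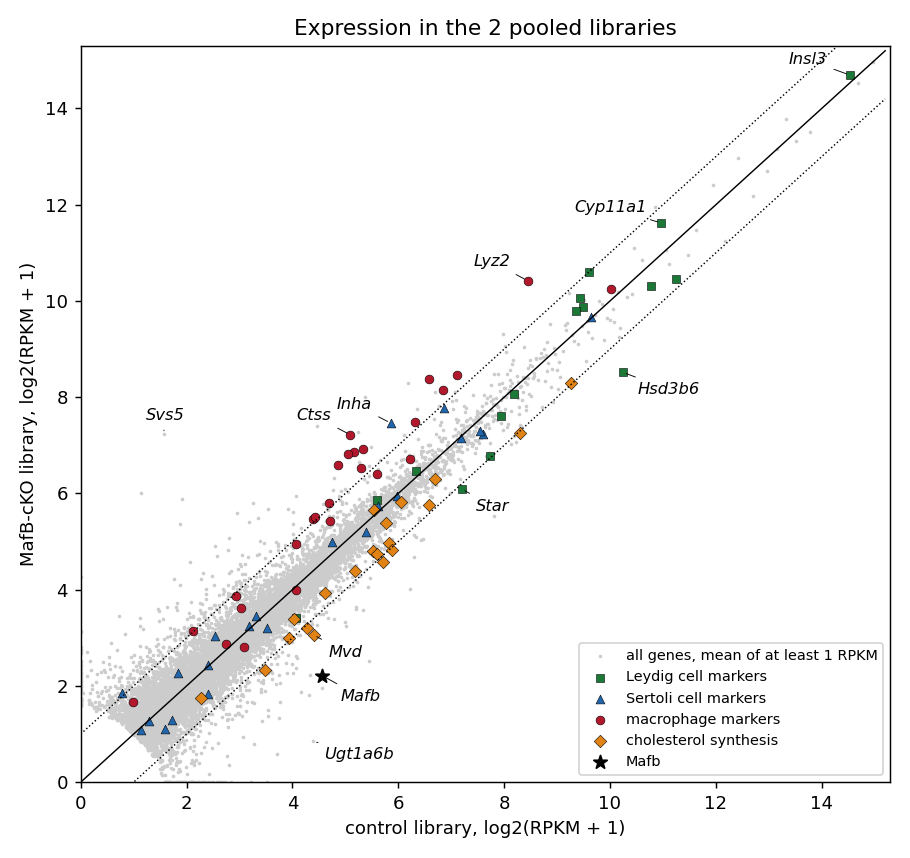
Each point is 1 gene, with its level in the control library on the horizontal axis and in the MafB-cKO library on the vertical axis, both as log2(RPKM + 1), for the 11786 genes with a mean of at least 1 RPKM; the solid line marks equal values and the dotted lines a 2-fold difference. Mafb lies below the lower dotted line at 22.7 and 3.64 RPKM, 15 of 26 macrophage markers lie above the upper dotted line, 19 of 20 cholesterol synthesis genes lie below the solid line, and Insl3 lies near the top of both axes.

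The largest log2 fold toward MafB-cKO among genes with a mean of at least 5 RPKM was that of Svs5. This gene, which codes for a seminal vesicle secretory protein (chromosome 2, 164332740 to 164334396), was at 1.97 RPKM in the control and 149 RPKM in MafB-cKO, a log2 fold of 5.66. Its neighbour Svs6 (chromosome 2, 164316751 to 164318453) was listed at 0 in the control and at 18.2 RPKM in MafB-cKO. Lyz1, a lysozyme gene on chromosome 10 from 117287797 to 117292868, was at 1.22 and 63.4 RPKM. Its paralog Lyz2, next to it from 117277331 to 117282321, was at 348 and 1370.48 RPKM, so that the division of reads between the pair is uncertain. Myh6, the alpha heavy chain of cardiac myosin, was at 2.79 and 57.9 RPKM, with uncertainty from its close paralog Myh7. Inf2, a formin that acts on actin filaments, was at 2.67 and 40.2 RPKM, and the water channel gene Aqp5 was at 6.73 and 47.3 RPKM. The acyl-CoA thioesterase gene Acot1, which has near-identical relatives, was at 21.2 and 168 RPKM. Klk1, a tissue kallikrein, was at 40.4 and 256 RPKM, and Lgals3, which codes for the lectin galectin-3, was at 8.6 and 54.8 RPKM. The prostaglandin transporter gene Slco2a1 had a log2 fold of 2.51, the neutrophil chemokine gene Cxcl2 of 2.46 and the U11 small nuclear RNA Rnu11 of 2.73.

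Toward the control, the largest log2 fold of a gene above 0 in both libraries was that of Ugt1a6b. This UDP-glucuronosyltransferase gene on chromosome 1 from 88103252 to 88219003 was at 20.0 RPKM in the control and 0.81 RPKM in MafB-cKO, a log2 fold of −3.54. The members of this locus share their 3′ exons, so the value of a single member is uncertain. Mfsd2a, a transporter of lysophosphatidylcholine, was at 12.1 and 0.511 RPKM, and the ribonuclease gene Rnasek was at 42.5 and 4.74 RPKM. Gata6, a transcription factor gene on chromosome 18 from 11052064 to 11085635, was at 10.6 and 1.6 RPKM, a log2 fold of −2.16. Hist1h2ba, a testis histone H2B variant, was at 16.8 and 2.66 RPKM, and the mitochondrial serine transfer RNA mt-Ts2 was at 10.5 RPKM in the control and listed at 0 in MafB-cKO. Klk1b22, 1 of a family of closely similar kallikrein genes, was at 223 and 45.5 RPKM. The lectin gene Cd209f had a log2 fold of −1.78 and the aldehyde dehydrogenase gene Aldh3a1 of −1.75, with Ttc36 at −2.10 and Sv2c at −2.05.

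Among the 29 lists that were fixed before the data were examined and had a percentile, macrophage markers had the highest median in MafB-cKO. All 26 macrophage markers were measured, of which 15 were at least 2-fold higher, 11 were within 2-fold and none was 2-fold lower. Their median log2 fold was 1.08 (quartiles 0.67 and 1.53), at percentile 100 of 10000 random lists matched on level. The central 95% of the random medians ran from −0.16 to 0.12. The median marker was at 30.03 RPKM in the control and 87.7 RPKM in MafB-cKO. Ctss, the lysosomal protease cathepsin S, was at 33.2 and 148 RPKM, and Lyz2, the lysozyme of myeloid cells, had a log2 fold of 1.98. The antigen presentation genes Cd74 and H2-Aa were at 94.5 and 31.97 RPKM in the control and at 333 and 112 RPKM in MafB-cKO. Not all markers were higher, as the mannose receptor gene Mrc1 had a log2 fold of −0.07 and the scavenger receptor gene Cd163 of −0.28. Mrc1 and Cd163 were chosen after their values were seen.

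Genes reported to depend on MAFB in macrophages and podocytes had a higher median in the knockout library, which rested in part on members shared with other lists and depended in size on the pseudocount and the minimum level. Of 12 measured members, 6 were at least 2-fold higher and none was 2-fold lower, with a median log2 fold of 0.83 at percentile 100. A pseudocount of 5 gave a median of 0.35 at percentile 99.99, and no minimum level gave 0.36 at percentile 99.97 over 17 members. The complement genes C1qb and C1qa were at 137 and 114 RPKM in the control and at 350.0 and 284 RPKM in MafB-cKO, and C1qc had a log2 fold of 1.16. Marco, a scavenger receptor of macrophages, was at 0.284 and 2.06 RPKM. Of the podocyte genes, Podxl was lower, at 3.72 and 1.71 RPKM with a log2 fold of −0.80, and Nphs1 and Nphs2 were below the minimum level. These podocyte genes were chosen after their values were seen. The macrophage markers with their median of 1.08 were higher in the same library. The 7 members found in no other list had a median of 0.36 at percentile 97.1, inside the central 95% of random lists, so that without shared members this list no longer stood apart.

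Cytokine and interferon genes were also higher as lists, beside the macrophage median of 1.08. Of 14 inflammatory cytokine and chemokine genes, 3 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 fold of 0.47 at percentile 99.98. Cxcl2 was at 2.39 and 17.7 RPKM, the interleukin genes Il1b and Il18 had log2 folds of 1.64 and 1.05, and the chemokine gene Cxcl5 was at 3.38 and 0.574 RPKM. Of 15 interferon-stimulated genes, 1 was at least 2-fold higher and none 2-fold lower, with a median of 0.39 at percentile 99.97. That gene was Oas1a, an oligoadenylate synthetase, at 1.17 and 6.10 RPKM. Oasl2 had a log2 fold of 0.92 and Ifi27l2a of 0.80, while Mx2 had −0.76. Lymphocyte and other leukocyte markers were near the lower end of the scale, with medians over all members of 0.293 and 0.302 RPKM. Their 5 measured members had a median log2 fold of 0.14 at percentile 76.5. S100a8, a neutrophil calcium-binding protein gene, was at 0.885 and 3.54 RPKM, and the cytotoxic granule gene Nkg7 was at 1.90 and 0.251 RPKM.

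**Figure D2:**
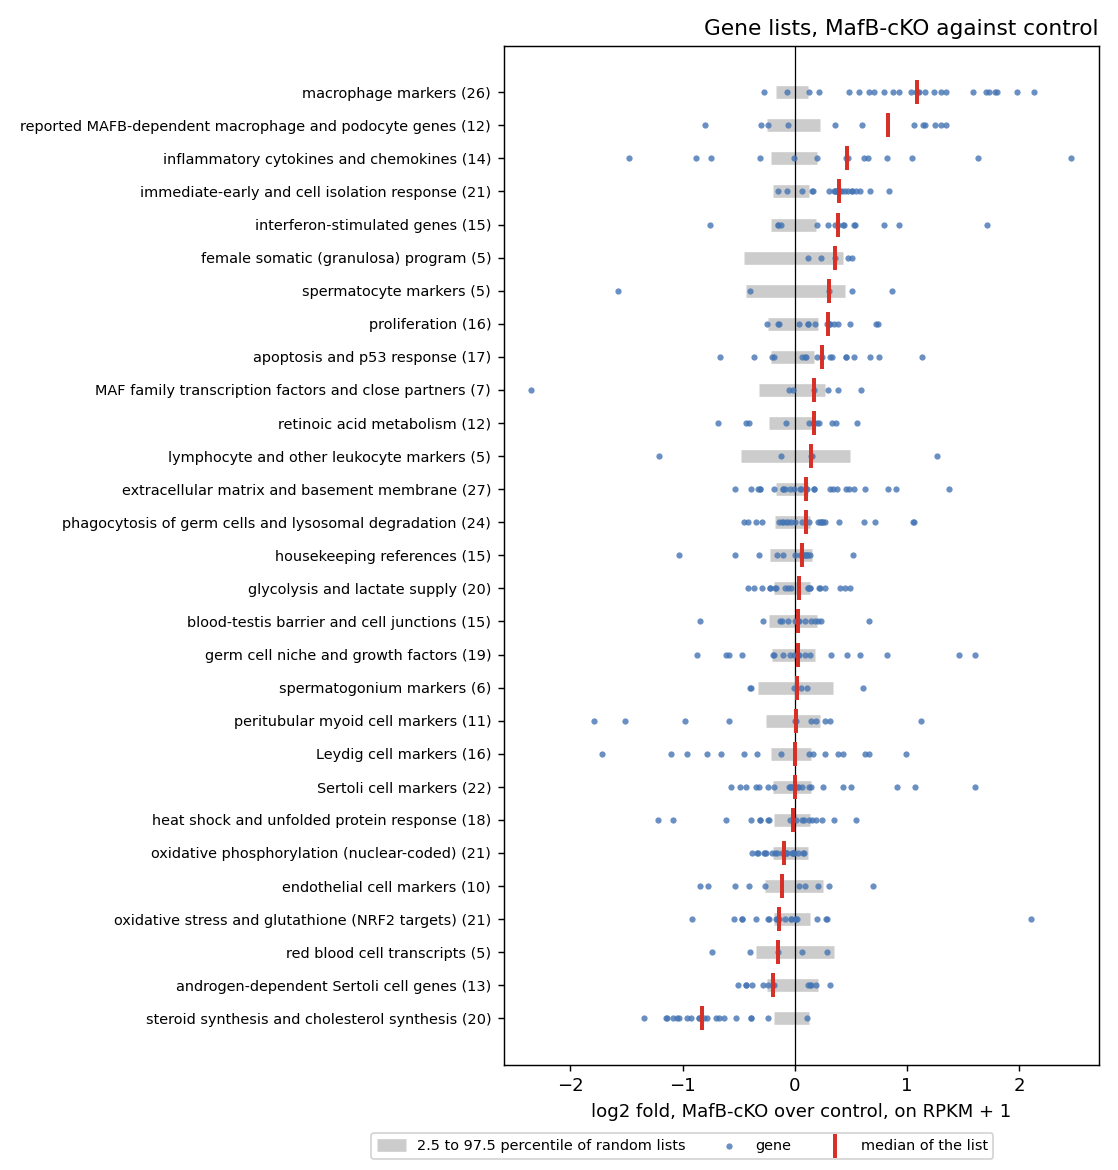
Each row is 1 gene list with its number of measured genes, each blue point the log2 fold of 1 gene (MafB-cKO over control, on RPKM + 1), each red bar the list's median, and each grey bar the central 95% of the medians of random lists matched on level. The medians of 7 lists lie to the right of their grey bars, led by macrophage markers at 1.08, and the cholesterol synthesis median at −0.83 lies to the left.

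Genes of cholesterol synthesis were lower in MafB-cKO, the only list of the 29 with a percentile whose median lay below the random lists. All 20 members were measured: 19 had lower values and 1 a higher value, and 6 were at least 2-fold lower. The median log2 fold was −0.83 (quartiles −1.04 and −0.61), at percentile 0. Macrophage markers, with a median of 1.08, differed between the same libraries in the other direction. The mitochondrially encoded mRNAs, a list written after the values were seen, had a median of −0.67 with 12 of 13 values lower. Mvd, mevalonate diphosphate decarboxylase (chromosome 8, 122433601 to 122443422), was at 20.1 RPKM in the control and 7.34 RPKM in MafB-cKO. The isoprenoid isomerase gene Idi1 had a log2 fold of −1.15, the sterol dehydrogenase gene Nsdhl of −1.14 and the phosphomevalonate kinase gene Pmvk of −1.09. The most abundant member, Dhcr24, which codes for the last reductase of the pathway, was at 612 and 314 RPKM, and it was chosen after its values were seen.

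Markers of Leydig cells, the testosterone-producing cells between the tubules, were abundant in both libraries, and their list lay within the random range. The 16 measured markers had a median log2 fold of 0.00 at percentile 62.7, with 2 at least 2-fold lower and none 2-fold higher; with no minimum level, the median was 0.13 at percentile 98.4. Hsd3b6, a 3β-hydroxysteroid dehydrogenase of adult Leydig cells, was at 1209 and 366 RPKM. Its close paralog Hsd3b1, with which reads can be shared, was at 690 and 1061 RPKM and was chosen after its values were seen. Star, which carries cholesterol into mitochondria, was at 146 and 67.3 RPKM, a log2 fold of −1.11. Ces1d, a carboxylesterase gene, was at 212 and 108 RPKM, and the kallikrein gene Klk1b27 was at 782 and 1553 RPKM. Insl3, the insulin-like hormone of Leydig cells (chromosome 8, 71689214 to 71690575), was at 23722 RPKM in the control and 26501 RPKM in MafB-cKO, rank 3 and rank 2 of all genes. Cyp11a1, which starts steroid synthesis, was at 1994 and 3152 RPKM and was chosen after its values were seen. The other genes among the highest 5 of either library were Metazoa_SRP_4, Metazoa_SRP_5, Rn7sk, Gm26924 and Gm26917, each above 10000 RPKM.

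Sertoli cell markers were less abundant than Leydig cell markers, and their list also lay within the random range. The median Sertoli marker was at 4.30 RPKM in the control and 4.09 RPKM in MafB-cKO, against 269 and 231 RPKM for the median Leydig marker, ratios of 62.6 and 56.4. Over 10 further markers of each type, listed before their values were looked at, the ratios were 5.11 and 3.48, so the size of the gap depended on the markers. The sex determination factor gene Sox9 was at 0.627 and 0.998 RPKM, Amh, anti-Müllerian hormone, at 0.388 and 0.260 RPKM, and Fshr, the receptor for follicle-stimulating hormone, at 0.315 RPKM in the control and listed at 0 in MafB-cKO. Wt1 was at 1.20 and 1.13 RPKM, the junction gene Cldn11 at 4.27 and 4.38 RPKM, and the androgen receptor gene Ar at 4.33 and 2.59 RPKM. Gata4, which Leydig cells also express, was at 62.3 and 60.6 RPKM. Of 22 measured markers, 2 were at least 2-fold higher and none 2-fold lower, with a median log2 fold of 0.00 at percentile 62.6. Those higher were Inha, the inhibin alpha subunit, at 57.0 and 175 RPKM, and Mro at 0.728 and 2.62 RPKM, while Vim, vimentin, had a log2 fold of 0.91. Which cells the Inha, Mro and Vim transcripts came from was not tested, so their folds cannot be read as changes in Sertoli cells.

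**Figure D3:**
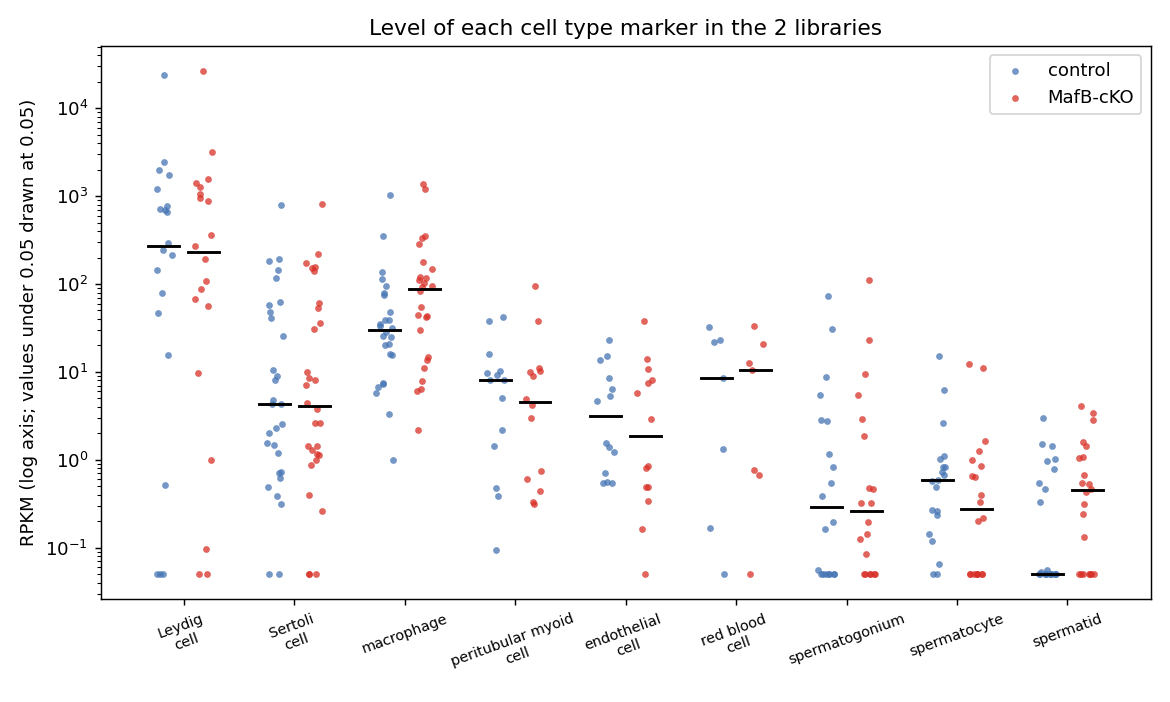
Each point is 1 marker gene in 1 library, with its RPKM on a logarithmic vertical axis (values under 0.05 drawn at 0.05), for 9 cell types; blue is the control, red is MafB-cKO, and black bars are medians. Leydig cell markers have medians of 269 and 231 RPKM, Sertoli cell markers 4.30 and 4.09 RPKM, and macrophage markers 30.03 and 87.7 RPKM.

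Lists of genes for functions of Sertoli cells had medians within the random range. The median Sertoli marker was at 4.30 and 4.09 RPKM, against 269 and 231 RPKM for the median Leydig marker, in control and MafB-cKO. These medians therefore cannot be read as functions of Sertoli cells alone. Blood-testis barrier and junction genes had a median log2 fold of 0.03 at percentile 67.4, and none of the 15 measured was past 2-fold. The nearest were Cldn5 at −0.84, a claudin also found in endothelium, and Jam2 at 0.66. Androgen-dependent Sertoli cell genes had a median of −0.19 at percentile 7.31, with none of 13 past 2-fold. Fabp3, a fatty acid-binding protein gene, was at 2841 and 1994 RPKM. Germ cell niche and growth factor genes had a median of 0.03 at percentile 68.3, with 2 of 19 at least 2-fold higher, Inha and the cytokine gene Lif, which was at 0.256 and 2.46 RPKM. The chemokine gene Cxcl12 was at 46.3 and 24.8 RPKM and the platelet-derived growth factor gene Pdgfb had a log2 fold of 0.82. Genes of germ cell phagocytosis and lysosomal degradation had a median of 0.10 at percentile 93.6, with the receptor gene Axl and its ligand gene Gas6, at 1.06 and 1.05, the 2 of 24 at least 2-fold higher. Both Axl and lysosomal genes are also expressed by macrophages, whose list median was 1.08. Glycolysis and lactate supply genes had a median of 0.04 at percentile 78.0, with none of 20 past 2-fold, and lactate dehydrogenase Ldha at 39.0 and 55.2 RPKM. Retinoic acid metabolism genes had a median of 0.17 at percentile 96.7 (98.9 with no minimum level), with none of 12 past 2-fold, and the retinol-binding protein gene Rbp1 at 35.6 and 21.8 RPKM.

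Stress response genes were higher as a list for immediate-early genes and about level for heat shock genes. The 21 measured immediate-early genes, which cell isolation is known to induce, had a median log2 fold of 0.39 (quartiles 0.31 and 0.51) at percentile 100, with 19 higher values, 2 lower values and none past 2-fold. The transcription factor genes Atf3, Fosb and Jund had log2 folds of 0.84, 0.67 and 0.58, and Fosb was at 224 and 356 RPKM. Macrophage markers, with a median of 1.08 and 15 of 26 past 2-fold, were higher in the same library. Heat shock and unfolded protein response genes had a median of −0.02 at percentile 53.7, with 2 of 18 at least 2-fold lower, the chaperone genes Hsp90aa1 at 7.17 and 2.5 RPKM and Hsp90b1 at 16.6 and 7.29 RPKM. Glutathione and antioxidant genes had a median of −0.14 at percentile 8.54, yet Gpx3, an extracellular glutathione peroxidase, was at 72.0 and 312 RPKM, a log2 fold of 2.10. Gsta3 and Gstm1, glutathione transferases with close paralogs, had log2 folds of −0.92 and −0.54. Nuclear genes of oxidative phosphorylation had a median of −0.09 at percentile 20.0, with none of 21 past 2-fold and Cox6c at −0.39.

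Cell cycle and p53 response genes had medians above the central 95% of random lists, with small folds, beside the macrophage median of 1.08. The 16 proliferation genes had a median log2 fold of 0.29 at percentile 99.6, with 13 higher and 3 lower values and none past 2-fold. Ccnb2, cyclin B2, was at 1.61 and 3.37 RPKM and the mitotic kinase gene Aurka at 2.03 and 4.004 RPKM. With a mean of at least 5 RPKM required, 5 members were left and their percentile was 90.4. The 17 apoptosis and p53 response genes had a median of 0.24 at percentile 99.57, with 1 at least 2-fold higher, the cell cycle inhibitor gene Cdkn1a at 29.1 and 65.0 RPKM. Casp3, Bcl2l1 and Gadd45a had log2 folds of 0.75, 0.67 and −0.66. With no minimum level, the percentile of this list was 96.1.

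Markers of the remaining testis cell types had median levels far below those of Leydig cells in both libraries. Peritubular myoid cell markers had a median log2 fold of 0.01 at percentile 60.7 over 11 genes, with members on both sides: the smooth muscle genes Acta2 and Tagln had −1.52 and −1.79, and Aebp1 had 1.12. Endothelial markers had a median of −0.11 at percentile 21.5 over 10 genes, and of −0.30 at percentile 1.20 with no minimum level, with Pecam1 at 1.55 and 0.491 RPKM. Red blood cell transcripts had a median of −0.15 at percentile 21.1 over 5 genes, and the alpha globin genes Hba-a1 and Hba-a2, which are near-identical, had −0.74 and −0.15. Spermatogonium markers had a median level of 0.292 RPKM in the control and 0.258 RPKM in MafB-cKO, and 6 measured members had a median log2 fold of 0.02 at percentile 60.4. The highest of them, Kit, which Leydig cells also express, was at 72.8 and 111 RPKM. Spermatocyte markers had medians of 0.587 and 0.274 RPKM, and 5 measured members had a median log2 fold of 0.31 at percentile 93.6, with Tex101 at −1.57 and Ldhc at 0.87. With no minimum level, 19 members were counted and the direction turned, with a median of −0.24 at percentile 1.07. Of the spermatid markers, 4 were measured, too few for a percentile, among them the protamine gene Prm2, listed at 0 in the control and at 4.13 RPKM in MafB-cKO, and Prm1 at 1.49 and 2.80 RPKM. Of the rete testis and epididymal epithelium markers, 3 were measured, and Lcn2, lipocalin 2, was at 4618 and 2416 RPKM, while most of the others were near 0.

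The remaining lists lay within the random range. Extracellular matrix and basement membrane genes had a median log2 fold of 0.10 at percentile 95.4, with 1 of 27 at least 2-fold higher, the fibronectin gene Fn1 at 2.11 and 7.05 RPKM. The fibrillar matrix genes Dcn and Col3a1 had log2 folds of 0.90 and 0.83. The female somatic program had 5 measured members with a median of 0.35 at percentile 95.3, and Rspo1 was at 1.32 and 2.23 RPKM. Housekeeping references had a median of 0.06 at percentile 83.1, with Actb at 729 and 1044 RPKM and the transferrin receptor gene Tfrc, at 2.66 and 0.784 RPKM, the 1 of 15 past 2-fold. In all, 7 of the 29 lists with a percentile lay above the central 95% of random lists and 1 below it. If genes moved independently, 1.45 of 29 would lie outside, but genes of a list can move together, and the lists share members. A percentile describes these libraries only and does not test the effect of the knockout.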

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

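All alternatives here were planned except tied zeros set to 0, 10 level bins, the macrophage list without complement C1q, MHC class II and Cd74 genes, and the lists without shared members, which were chosen after the values were seen. The counts of genes past 2-fold, 400 higher and 286 lower, moved with the threshold, the pseudocount and the minimum level. A pseudocount of 0.1 gave 666 higher and 547 lower, a pseudocount of 5 gave 96 and 60, no minimum level gave 543 and 438, and a mean of at least 5 RPKM gave 177 and 103 over 6423 genes. Requiring 1.5-fold gave 1039 and 909, and 4-fold gave 59 and 52; these follow from the thresholds themselves. The higher share stayed between 53.2% and 63.2% over all settings, and from 54.1% to 60.3% over the scalings. Mafb had a log2 fold of −1.68 with a pseudocount of 5 and from −2.61 to −2.34 under the other settings run on it. Upper-quartile scaling had a factor of 1, moved nothing and says nothing about stability. The scalings by median ratio and trimmed mean had factors of 1.01 and 0.972 and left 7 lists above the central 95% of random lists and 1 below it. As 1 factor moves a list and its random lists nearly alike, these percentiles could hardly change, and this says little about stability. With no minimum level, 8 lists lay above and 3 below, and the spermatocyte list went from a median of 0.31 to −0.24 (percentile 1.07), as genes near 0 entered; the cause was not tested further. Of 282 list values under alternatives, 273 kept their place inside or outside the random lists and moved by under 0.46. That bound is wide: the inflammatory and interferon medians of 0.47 and 0.39 fell as low as 0.25 and 0.22. For lists that stayed inside the random range, a change of sign was not counted. Of the others, 3 lost their place outside the random lists: proliferation, apoptosis, and the MAFB-dependent list without shared members (median 0.36, percentile 97.1). With no minimum level, a further 3 gained one: Leydig cell markers (median 0.13, percentile 98.4), endothelial markers (−0.30, 1.20) and retinoic acid metabolism (0.16, 98.9). Another 2 moved, both of the MAFB-dependent list, whose median of 0.83 became 0.35 with a pseudocount of 5 and 0.36 with no minimum level, and 1 reversed. Macrophage markers stayed at percentile 100 and cholesterol synthesis at percentile 0 under every setting run on them, with medians from 0.87 to 1.13 and from −0.87 to −0.72. The macrophage median was 0.87 without complement C1q, MHC class II and Cd74 genes and 1.03 without members found in another fixed list; the interferon and inflammatory lists share no members with these and kept 0.39 and 0.47. Of 900 log2 folds of named genes, 50 moved, all with a pseudocount, and none reversed. A pseudocount changes the size of a log2 fold but cannot change its sign. The scaling factors lay too near 1 to move a fold past the bound. Setting tied zeros to 0 could not move these folds, as genes at a tied zero were given none. The absence of reversals therefore says nothing about stability, and only the pseudocounts tested the size of these folds. No paired analysis was possible because each group is 1 pooled library. As the depth is unknown, counting error could not be set against any difference.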

Other observations

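The gene lists in this paragraph and the next, apart from nuclear oxidative phosphorylation and the further Leydig and Sertoli cell markers, were written after their values had been seen, so they give descriptions only. Sterol-regulated genes outside the fixed cholesterol list were also lower in MafB-cKO: 20 of 24 measured members had lower values, with a median log2 fold of −0.39 at percentile 0. Acat3, Tm7sf2 and Acat2, which act in acetyl-CoA and sterol metabolism, had log2 folds of −1.52, −1.36 and −1.16, while the fatty acid desaturase gene Fads2 was at 1171 RPKM in the control and 690 RPKM in MafB-cKO. Abcg1, a cholesterol exporter gene, and Lpl, lipoprotein lipase, went the other way, with 0.96 and 1.03. Of the mitochondrially encoded mRNAs, 12 of 13 had lower values in MafB-cKO, with a median of −0.67 at percentile 0, whereas the mitochondrial ribosomal RNA mt-Rnr1 was at 1842 and 3941 RPKM and mt-Rnr2 at 5482 and 8015 RPKM. The nuclear oxidative phosphorylation genes had a median of −0.09.

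Within the UDP-glucuronosyltransferase 1 family, 4 members were measured, with a median log2 fold of −1.16, and Ugt1a6a and Ugt1a7c, with Ugt1a6b, had log2 folds of −0.91, −1.40 and −3.54, on transcripts that share their last exons. The kallikrein 1 family went both ways, with a median of 0.38 at percentile 99.9: Klk1 had 2.64 and Klk1b22 −2.27, and reads of its closely similar members can be shared. Of 18 cardiac muscle transcripts, 3 were measured, Myh6 at 3.96, Myh7 at 1.65 and Tnni3 at 0.69, while Nppa, Myl2 and Csrp3 were listed at 0 in both libraries. Of 14 seminal vesicle secretory transcripts, Svs5 and Svs6 were the 2 measured. The 7 measured Sertoli-restricted transcripts had a median log2 fold of 0.06 at percentile 70.8. Over all 14 members, the median level was 1.93 RPKM in the control and 1.37 RPKM in MafB-cKO. These levels stood at percentiles 17.2 and 8.79 of genes with a mean of at least 1 RPKM. The 10 further Leydig cell markers had a median of −0.15 at percentile 17.1 and the 8 measured further Sertoli cell markers a median of −0.05 at percentile 40.7.

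The tests in the rest of this part were chosen after the pattern was seen, and all but those on further Leydig and Sertoli cell markers and on the residual after a trend with GC content, transcript length and level after the values they use. Leydig cell transcripts exceeded Sertoli cell transcripts in both libraries, by ratios of list medians of 62.6 and 56.4, although the labels name sorted Sertoli cells checked for purity by staining, a sort that should remove Leydig cells. Sertoli cells with some Leydig cell RNA carried over would keep Sertoli transcripts abundant. The median of the 10 further Sertoli markers stood at percentiles 27.7 and 33.1, below the middle of measured genes, the bound set beforehand. No library of pure Sertoli cells was at hand to place that bound. Members ran from Erbb4, listed at 0 in both libraries, to Cited1 at 35.4 RPKM in the control and Tesc at 21.4 RPKM in MafB-cKO. The median Sertoli-restricted transcript stood lower, at percentiles 17.2 and 8.79, but that list was written after its values were seen. Both medians go against mostly Sertoli cells. With no reference library and members this spread out, carried-over RNA is not excluded. That most sorted cells were Leydig cells is a candidate explanation left open: the median further Leydig marker, with Fdxr at 163 and 147 RPKM and Sult1e1 at 107 and 119.5 RPKM, was 5.11 and 3.48 times the median further Sertoli marker, above 1 but below the 10 times set as the bound in its favour. Quantile normalization keeps the order of genes within a library but can alter the size of a ratio, which stays open; a gap of 57.9 and 59.2 percentile points between the list medians and a share of 75.3% and 75.5% of marker pairs with the Leydig gene higher restate the pattern and test nothing. Neither a sample exchange nor a biological explanation was tested.

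Macrophage transcripts were higher in MafB-cKO, with a list median of 1.08, from Lyz2 at 348 and 1370.48 RPKM down to Ptprc at 0.998 and 2.16 RPKM; 3 of the 26 genes stand in another fixed list and 7 more in lists written later. Scaling of the libraries by 1 factor is argued against, since 1 factor moves all genes alike. The list median lay 1.10 above the median of genes outside the macrophage lists. Quantile normalization is not 1 factor, and its effect could not be tested. A trend with GC content, transcript length and level is also argued against. It explained 2.00% of the variance of log2 folds, so the median residual of 1.10 after its removal says little. However, the highest median of 10000 lists matched on these properties was 0.41, against 1.09 for the 25 markers that have them. A smaller share of the main cell type alone would raise other cell types alike. The highest median among myoid, endothelial and red blood cell lists was 0.0068, with myoid quartiles of −0.78 and 0.23. Lists not in that comparison had medians of 0.14 (lymphocytes and other leukocytes), 0.31 (spermatocytes) and 0.38 (spermatids), over few measured genes. All lie below the macrophage median of 1.08, but other changes in composition are not excluded. A larger share of the same macrophages cannot be told apart from a different kind of macrophage: MHC class II and monocyte-derived markers (13 genes, median 1.73, percentile 100) exceeded resident markers (13 genes, median 0.29, percentile 99.7) by 1.44, but by 0.11 over the 8 and 5 genes whose values had not been seen before the lists were written. The loss of MAFB itself, which may act in macrophages that passed the sort, stays open and untested, as 1 library per group confounds it with any difference between sorts.

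Svs5 and Svs6 were at 149 and 18.2 RPKM in MafB-cKO and at 1.97 RPKM and listed at 0 in the control. Seminal vesicle tissue carried along would bring Svs2, Svs3a, Svs3b and Svs4, of which the highest was at 0.0108 RPKM in MafB-cKO, a value that stands for a tied zero. DNA of another strain flanking the targeted allele, acting across the region, would raise the share of genes past 2-fold near Mafb; within 10 Mb it was 4.95% of 182 genes (95% exact binomial interval 2.29% to 9.18%), against 5.69% elsewhere. Of the 4 windows examined, those of 2, 5 and 20 Mb gave 0%, 5.43% and 4.56%. A local variant near Svs5, which lies 3.97 Mb from Mafb and may differ with the targeted allele, and an effect of the knockout stay open and untested.

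The lower cholesterol synthesis genes were examined before Svs5 and Svs6 replaced them among the patterns weighed. Of 16 measured Leydig cell markers, 11 had a log2 fold above the upper quartile of the cholesterol list, −0.61. The median over all genes outside the macrophage lists was −0.02.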
